A study of Mus musculus with 8 samples.

How the data were processed

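RNA from parotid glands of 16-week-old male mice was measured on 8 one-colour microarrays, 4 from db/db mice and 4 from db/m mice. Per the labels, ribosomal RNA was removed, the remaining RNA was amplified by random priming into Cy3-labelled cRNA, and the label was meant to cover whole transcripts. The design text describes 4 db/db mice and does not spell out that each db/m array is a separate animal, so p-values measure the spread between these samples. Groups came from the sample titles.

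Per the file headers, the authors deposited spot intensities read with Agilent Feature Extraction 11.0.1.1, among them a processed intensity that the software had corrected for background. No step between arrays had been applied to them. The authors also deposited a table of log2 values for 60641 probes, with no method given in the sources used here. Of its values, 91.3% lay within 0.01 of a quantile normalization of the processed intensities, and each column correlated best with its own array (r from 0.996 to 0.998). Its column medians were all 6.51, its genes were not centred, and the direction of db/db against db/m was thereby settled. That table held no value for the probes named by gene below.

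Each array carried 62976 spots, of which 1439 were control spots. For the main values, log2 of the processed intensity was taken, the 75th percentile of the array's non-control spots was subtracted, spots the software marked as non-uniform or as population outliers were left out (18 to 55 per array), and spots of one probe were averaged. No non-control spot was saturated. A further 132 probes with series names other than those tested (MM9NEGATIVE, ASSPINKEIN and CUST) were set aside. Of 60691 probes, 54638 were well above background on at least 4 of the 8 arrays and were tested. Between 85.3% and 92.3% of spots per array were well above background, and the 75th percentile signal lay between 317.3 and 378.7. The number of arrays limits the precision.

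Gene names were matched by accession. The files pair 50 probes, each printed as 10 spots, with an accession, and 46 of these matched a gene in a RefSeq table of assembly GRCm38.p6. Of the 46, 45 were protein coding and 1 was a transcribed pseudogene. The design header names another build, so no coordinates are given. The lncRNA class held 29618 probes with LNC or lincRNA in their names, plus the probe of the pseudogene Rps4l, whose accession is non-coding. The AP1B series (22359 probes), the P series (7912) and the UP series (752) carry no gene or class in the files used here and are counted apart.

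The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, db/db minus db/m), and p-values were adjusted by Benjamini-Hochberg over all 54638 probes. A probe was called at an adjusted p below 0.05. Fold changes are given as log2 differences with standard errors. Single values outside that fit were compared by exact permutation tests, two-sided, whose smallest p with 4 against 4 is 0.0286. A probe not well above background on any array of a group has only a bound there. The bound sets the bright group's mean against, per array, the higher of the dim probe's own value and the lowest signal among probes well above background. The fit was tested on simulated data with the real means and spreads of 54590 probes. Of 100 probes shifted by 1 on the log2 scale it recovered 66, of 100 shifted by 0.5 it recovered 9, and it called 4 unchanged probes. Only 200 probes were shifted there, while 27.8% of the real probes were called. The adjustment is stricter when few probes change, so these shares do not carry over to the real data. Noise was drawn independently for each probe, without effects shared by many probes, so the 4 unchanged probes called do not carry over either. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

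The groups, the test, the gene lists and the rule for naming genes were fixed before the data were examined. The rule took the 10 largest rises and 10 largest falls among called protein coding genes whose groups did not overlap, passing over genes known only by a model number. It also took 5 and 5 lncRNAs, of which 2 and 2 are given here, up to 4 called members of each list, Lepr and Leprot, and called members of a list of well known lncRNAs. Of 36 lists with 917 members, 5 lists had a named probe and the fullest had 3 members, below the minimum of 5, so the planned list test was not run. Lepr, Leprot and the well known lncRNAs had no named probe and were not analysed here. No measured protein coding gene that the rule names was left out; 1 further entry of the rule, without a named probe, is not described here.

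Results were recomputed with quantile normalization, normexp background correction with an offset of 50, another probe set behind the percentile, the authors' log2 table, other filters on dim probes, other eBayes and array weight settings, a replicate block, leaving out each array, and thresholds of 2-fold. The files used here hold no mean spot signal, so normexp was run on the median spot and background signals. All arrays lay on 1 slide and came from 1 scan. The db/m arrays lay in row 1 and the db/db arrays in row 2, so slide row and group cannot be told apart. Each of the 4 slide columns held 1 array of each group.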

Results

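Transcripts of the parotid gland, the salivary gland in front of the ear, were measured in db/db mice, which lack a working leptin receptor and serve as a model of type 2 diabetes, and in db/m mice, the age-matched comparison group. There were 4 arrays per group. Over 54590 probes with a value on every array, correlations ran from 0.987 to 0.995 within groups and from 0.972 to 0.982 between groups. The first principal component held 58.1% of the variance and separated db/db from db/m.

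The first comparison asked which coding transcripts differ between the glands of db/db and db/m mice. Among genes with a named probe, Hyal3, a hyaluronidase family member, was 2.21-fold higher in db/db, and Mzb1, an endoplasmic reticulum protein of B and plasma cells, was 2.13-fold higher. Gsdmd, which encodes the pore-forming protein of pyroptosis, was 2.08-fold higher, and Duox1, a hydrogen peroxide-producing oxidase, was 1.89-fold higher. Apoe, an apolipoprotein, rose 1.89-fold and Gpi1, a glycolytic isomerase, rose 1.85-fold. Transcripts of Dnajc11, a mitochondrial DnaJ protein, and of Actb, the cytoskeletal beta-actin, fell. In all, 24 of 43 tested protein coding genes were called, 18 higher and 6 lower in db/db, and 29 when adjusted over the named genes alone. Over all tested probes 27.8% were called, and 57.1% of the called were higher. The 43 genes are those with a named probe, each averaged over 10 spots, and need not represent coding genes at large.

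Log2 intensity of Hyal3 was -0.65 ± 0.31 in db/db and -1.79 ± 0.05 in db/m (SD, n = 4 each), a difference of 1.14 ± 0.14 (SE, limma adjusted p = 0.000625). Mzb1 stood at 1.07 ± 0.33 against -0.02 ± 0.16, a difference of 1.09 ± 0.16 (adjusted p = 0.00143). Gsdmd differed by 1.06 ± 0.17 (adjusted p = 0.00192) and Gpi1 by 0.89 ± 0.10 (adjusted p = 0.000275). Duox1 and Apoe each differed by 0.92, with SE of 0.20 and 0.23 and adjusted p of 0.00898 and 0.0179. Prdx2, a peroxiredoxin that reduces hydrogen peroxide, rose by 0.78 ± 0.10. Bambi, a pseudoreceptor of the TGF-beta family, rose by 0.76 ± 0.12, Cav2, a caveolin, by 0.74 ± 0.11, and H2-Q7, a non-classical major histocompatibility gene, by 0.65 ± 0.16. The family of H2-Q7 has near-identical members that its probe may not separate. All 4 db/db values lay above all 4 db/m values for each of these 10 genes, as the naming rule required. That separation adds no separate support.

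Of the genes that fell, Dnajc11 differed by -0.61 ± 0.09 (adjusted p = 0.00113) and Actb by -0.55 ± 0.09 (adjusted p = 0.00176). Hspb7, a small heat shock protein, differed by -0.44 ± 0.08, the cytokine gene Il2 by -0.36 ± 0.09 and Tm9sf1, a membrane protein gene, by -0.32 ± 0.08. For each of these genes the 4 db/db values all lay below the 4 db/m values, which the naming rule required as well. Il2 had the dimmest of the tested named probes, at -4.35 ± 0.12 in db/db and -3.98 ± 0.09 in db/m (SD, n = 4 each). It was well above background on all arrays, but a difference at that level is less secure. With the slide column as a block, chosen after seeing the data, Apoe had an adjusted p of 0.0512. A block on the replicate numbers, which showed no sign of pairing the arrays, ended 5 of these calls, with adjusted p of 0.115 for Apoe, 0.0810 for H2-Q7, 0.0721 for Il2, 0.0679 for Hspb7 and 0.103 for Tm9sf1. Only the numbers 2, 5 and 8 occur in both groups, so this block takes db/db replicate 1 and db/m replicate 7 out of the comparison. It also leaves less information on the spread, so a call can be lost without any pairing. Without db/db replicate 5, H2-Q7 had 0.0511 and Il2 had 0.051, and Il2 had 0.102 with a trended and robust prior. With normexp the difference was 0.36 for Bambi, -0.27 for Hspb7 and -0.19 for Il2.

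**Figure D1:**
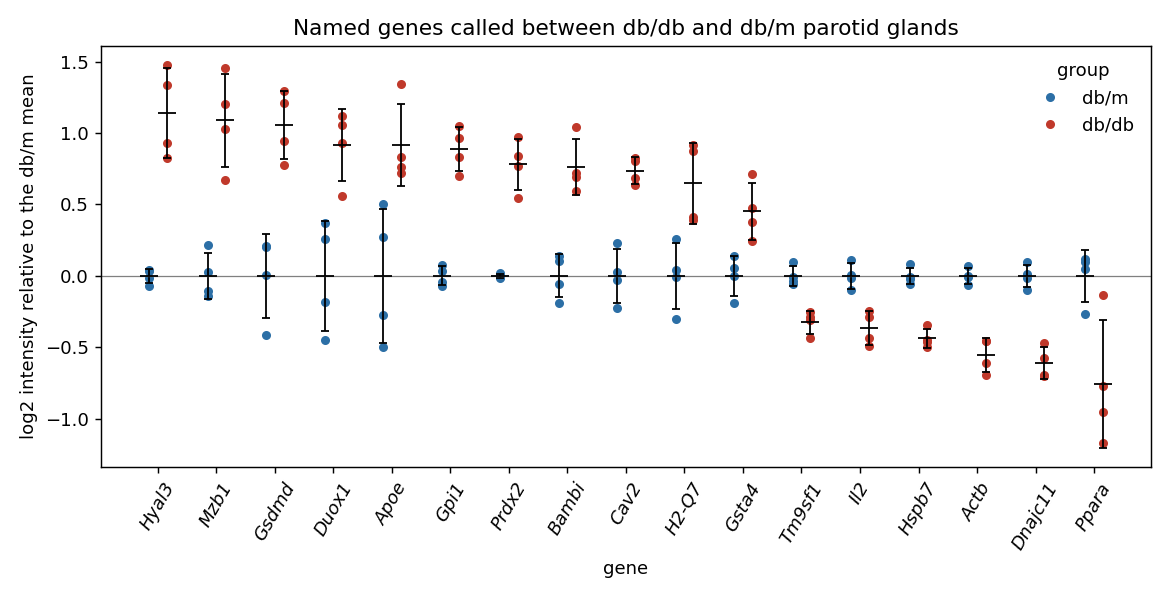
Log2 intensity of 17 called genes in each array, set against the gene's db/m mean, with db/m in blue and db/db in red. Points are arrays and bars are the mean ± SD (n = 4); Hyal3, Mzb1 and Gsdmd stand highest, and Ppara is the gene whose groups overlap.

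The fixed gene lists were covered by few named probes. In the oxidative stress response list, 2 of 34 members were measured and both rose, Prdx2 and the glutathione transferase Gsta4 (0.45 ± 0.12, adjusted p = 0.0211). Both were also called when adjusted over the list alone. That adds no support, since both had already passed over all tested probes. Gsta4 had an adjusted p of 0.0555 without db/m replicate 2 and 0.103 with the replicate block, and its difference was 0.30 with normexp. In the fatty acid oxidation and PPAR list, 1 of 3 measured members was called and 2 when adjusted over the list alone. Ppara, the nuclear receptor that drives fatty acid oxidation genes, fell by 0.76 ± 0.21 (adjusted p = 0.0244), with log2 intensities of -0.70 ± 0.45 in db/db and 0.05 ± 0.18 in db/m (SD, n = 4 each). The thiolase gene Acaa2 differed by 0.35 ± 0.12 (adjusted p = 0.0648) and the carnitine transferase gene Cpt1a by 0.18 ± 0.15 (adjusted p = 0.412). Acaa2 was called with normexp (adjusted p = 0.0239), with a trended and robust prior (0.0385) and without db/db replicate 2 (0.0173). The difference of Cpt1a was 0.31 without db/db replicate 2, 0.09 without db/db replicate 8 and 0.10 without db/m replicate 8. The groups overlapped for Ppara, since db/db replicate 1 stood at -0.08 and db/m replicate 8 at -0.21. Leaving out any 1 of 6 arrays (db/db replicates 2, 5 and 8, db/m replicates 2, 5 and 7) ended the Ppara call, with adjusted p from 0.0542 to 0.0696.

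Mzb1 was the single measured member of the plasma cell list. It was called over the list alone, which for 1 gene is no adjustment and adds no support. The autophagy gene Atg3 (0.01 ± 0.09) and the myelin gene Mbp (0.23 ± 0.12), the single measured members of the autophagy and of the Schwann cell list, were not called, with adjusted p of 0.928 and 0.202. Across 17 alternatives Atg3 ran from -0.04 to 0.06. The Mbp difference was 0.10 without db/db replicate 8 and 0.11 with normexp.

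The second comparison asked which long non-coding RNAs differ between the groups. Of 26643 lncRNA probes tested, 6869 were called, 3633 higher and 3236 lower in db/db. With normexp, 7325 were called, 3008 higher and 4317 lower, so the share of higher calls was 52.9% in one case and 41.1% in the other. It was 46.4% with quantile normalization. At a difference of at least 2-fold, 578 called lncRNA probes were higher and 641 lower. No gene name is paired with the lncRNA probes except Rps4l, a pseudogene of a ribosomal protein, which differed by 0.34 ± 0.27 (adjusted p = 0.391). Across 17 alternatives Rps4l ran from 0.16, without db/m replicate 7, to 0.62, without db/m replicate 8, where it was called (adjusted p = 0.0409), and it was 0.21 without db/db replicate 5.

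Called lncRNA probes without overlap between the groups were ranked if they were well above background on at least 1 array of each group. The background condition was not in the rule fixed beforehand. Of the ranked probes, ASMM10LNC1A100121683V4 rose most. Its log2 intensity was 0.33 ± 0.89 in db/db and -3.30 ± 0.28 in db/m (SD, n = 4 each), a 12.3-fold difference (adjusted p = 0.000252). The probe humanlincRNA1600-_P1V4 was 8.01-fold higher in db/db (adjusted p = 4.88e-05) and was well above background on 2 of 4 db/m arrays. Its db/m mean was -4.91 ± 0.49 (SD, n = 4), so the size of that fold rests in part on values near background. It is among 1092 probes named humanlincRNA, for which no mouse target is given. The largest fall among the ranked probes was that of ASMM10LNC1A102344788V4, which was 24.2-fold lower in db/db, at -1.95 ± 0.12 against 2.65 ± 0.54 (adjusted p = 2.54e-05). ASMM10LNC1A110860250V4 was 14.3-fold lower (adjusted p = 3.52e-05).

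Over all 54638 tested probes, 15173 were called, 8661 higher and 6512 lower in db/db. With normexp, 16203 were called, 7527 higher and 8676 lower, so the majority turned. It did not turn with quantile normalization, at 7661 higher and 7281 lower. In the AP1B series, 5929 of 20788 probes were called, 3382 higher and 2547 lower. With normexp, 3228 were higher and 3384 lower, so the majority turned there too. With quantile normalization, 3089 were higher and 2832 lower. In the P series, 2205 of 6651 were called, and 70.2% of the called were higher in db/db (58.1% with normexp). In the UP series 144 of 509 were called. The 4 db/db values lay all above or all below the 4 db/m values for 30.7% of the tested probes, where chance gives 2.86%.

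Some probes were detected in one group alone. On all 4 db/db arrays and no db/m array, 252 tested probes were well above background, 105 of them lncRNA probes, and 35 of the 252 were at least 2-fold higher by the bound. On all 4 db/m arrays and no db/db array, 20 probes were well above background, 11 of them lncRNA probes, and 10 of the 20 were at least 2-fold higher by the bound. The db/db arrays had 89.4% to 92.3% of spots well above background and the db/m arrays 85.3% to 89.3%.

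**Figure D2:**
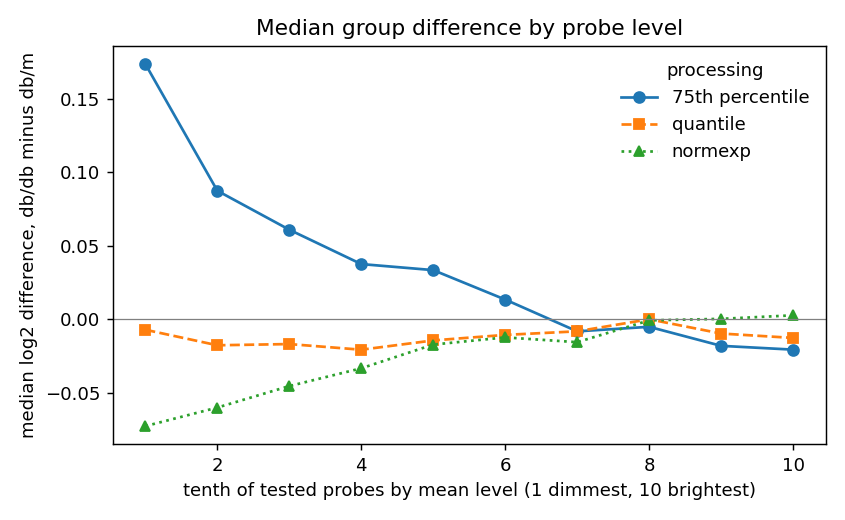
Median log2 difference, db/db minus db/m (vertical axis), in 10 equal sets of the tested probes by mean level (horizontal axis, dimmest at the left), under 3 kinds of processing drawn as lines. The dimmest set stood at 0.17 with percentile scaling, at -0.0073 with quantile normalization and at -0.07 with normexp.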

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

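The tests of slide row and RNA integrity were chosen after the results were seen, and the test of other splits of the arrays before.

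Control spots, which entered none of the comparisons, held mouse Gapdh and Pgk1 probes, both for glycolytic enzymes. Gapdh was higher in db/db than in db/m by 0.57 ± 0.10 (SE) at its 3' probe and by 0.30 ± 0.08 at its 5' probe, and Pgk1 was lower by a difference of -0.47 ± 0.08 at its 3' probe. Each had an exact permutation p of 0.0286, the smallest that 4 against 4 can give, and each kept its direction under quantile normalization, normexp and the other percentile. Actb, tested above, differed by -0.55 ± 0.09. Within each array, Gapdh minus Pgk1 at the 3' probes differed by 1.04 ± 0.07. RNA integrity stays open: the 3' minus 5' difference rose by 0.26 for Gapdh and differed by -0.19 for Pgk1, whose 5' probe was dim, between 30.1 and 39.0 in processed signal. A difference between db/db and db/m glands stays open as well.

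The number of called probes was large. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, called 15173 probes. The highest of the others called 0. A share of 1 in 35 is under the 0.05 set beforehand, but it is the smallest this design can give. The other splits mix the groups, so any group difference widens their spread and favours a count of 0. At an unadjusted p below 0.05 the real split had 21836 probes and the highest other split 6470. The counts of 24 protein coding genes, 6869 lncRNA probes and 5929 AP1B probes each stood against 0 in every other split. They come from the same splits, so they add no separate support. Slide row cannot be told apart from the group, since each group filled 1 row. Of 25 probes without a mouse target, 20% had an unadjusted p below 0.05, against 33.3% of tested probes of the same level. Without any difference between the rows or groups the share would be about 0.05. Among 90 ASSPINKEIN probes, whose target is not given, it was 24.4%. The probes without a mouse target lay above 0.05 but below the tested probes, which does not settle the part of slide row.

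Among 106 groups of 4 values tested for a value far from the others, 4 were found, and chance gives about 1 in 20. Anxa8 stood at -0.18 in db/db replicate 8, with the others between -0.73 and -0.69. Mbp stood at -1.23 in the same array, with the others between -1.76 and -1.69. Taf1a stood at 1.26 in db/db replicate 1, with the others between 0.94 and 1.00. The db/m replicate 5 array had 55 spots marked by the scanner software, with the others between 29 and 33. Of 15 CUST probes, which carry no gene name, 9 had all db/db arrays above all db/m arrays. CUST probes lying wholly the other way were not counted. Over all tested probes, 30.7% had groups without overlap in either direction.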

How the results depend on the processing

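The slide column block was chosen after seeing the data. Counts of called probes stayed within 1.5 times the main count under the other scalings, filters and priors, array weights, the slide column block and the authors' table, which holds no mRNA probe. Leaving out each array gave 10543 to 16173 probes, 18 to 24 coding genes, 4678 to 7332 lncRNA and 4234 to 6282 AP1B probes. At 2-fold with adjusted p below 0.05, 2824 probes, 3 coding genes (Hyal3, Mzb1 and Gsdmd), 1219 lncRNA and 1090 AP1B probes were called, and with unadjusted p 2936, 3, 1263 and 1118; the added size limit is the cause. With the replicate block the counts were 8521, 12, 3815 and 3191. This block takes db/db replicate 1 and db/m replicate 7, whose numbers occur in 1 group alone, out of the comparison. It also leaves less information on the spread, so fewer calls need not mean a pairing. No sign was seen that the numbers 2, 5 and 8 pair the arrays: same-numbered arrays had correlations of deviations of -0.02, -0.13 and -0.17, and 0 of 3 correlated best with their own number. The labels do not spell out what the numbers stand for, so 3 such correlations cannot exclude a pairing. Of 24 called genes, 11 were called under each of 17 alternatives, and 12 lost the call with the replicate block. No direction of a called gene reversed. The excess of higher calls may come from background treatment or from brightness left by percentile scaling. The dimmest of 10 equal sets of probes differed by 0.17 in the main values, by -0.0729 with normexp and by -0.0073 with quantile normalization, but the normexp offset compresses dim values and quantile normalization equalises the arrays, so both stay open, as does a difference between the glands. Slide and scan blocks were not run (1 slide, 1 scan), nor were the gene list tests and their alternatives; each gene had 1 named probe, so averaging probes moves nothing. Signal over background limits the dim probes.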

Other observations

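The genes in this part other than Actb lie outside the naming rule and were chosen after their values were seen. Kcnn2, a calcium-activated potassium channel gene, was higher in db/db by 0.53 ± 0.12 (SE, n = 4 each, limma adjusted p = 0.0104). Taf1a, a subunit of the RNA polymerase I selectivity factor, was higher by 0.53 ± 0.11 (adjusted p = 0.00861), Lhfp by 0.60 ± 0.10 (adjusted p = 0.00218, and 0.32 with normexp) and Carhsp1 by 0.45 ± 0.09 (adjusted p = 0.00547). With the replicate block Kcnn2, Taf1a and Carhsp1 had adjusted p of 0.0646, 0.0549 and 0.0766. H2-M2, another non-classical major histocompatibility gene, was higher by 0.53 ± 0.16 (adjusted p = 0.0395). Its values followed those of H2-Q7 from array to array. In db/db replicates 1, 2, 5 and 8 they were 4.34, 3.91, 4.44 and 3.90, against 6.08, 5.62, 6.12 and 5.59 for H2-Q7. Whether the rises of H2-Q7 and H2-M2 are separate was not tested. The H2-M2 call was lost without db/db replicate 1 or 5 and without db/m replicate 5, 7 or 8 (adjusted p from 0.0663 to 0.105), with no filter on dim probes (0.0518) and with the replicate block (0.133).

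Some other named genes did not pass. Pex11a, a peroxisome division gene, differed by -0.05 ± 0.09 (adjusted p = 0.73) and Rab5a, an early endosome GTPase gene, by 0.03 ± 0.10 (adjusted p = 0.833). Across 17 alternatives Pex11a ran from -0.08 to -0.01 and Rab5a from -0.02 to 0.08. The tyrosinase gene Tyr was well above background on none of the 8 arrays, and Gabrg1 on 2 db/db arrays and 0 db/m arrays, so neither was tested.

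Gapdh and Actb, both widely used as reference genes, moved apart. Within each array, Gapdh at its 3' probe minus Actb was 3.07 ± 0.27 in db/db and 1.95 ± 0.11 in db/m (SD, n = 4 each), a difference of 1.12 ± 0.15 (SE, exact permutation p = 0.0286, the smallest possible). With the 5' probe of Gapdh the difference was 0.86 ± 0.11. The size thus depended on the Gapdh probe, and the ratio does not show which of them changed.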
